A study of Mus musculus with 12 samples.

How the data were processed

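The repertoire of rearranged T cell receptor alpha (Tcra) transcripts was measured in CD4 and CD8 double-positive (DP) thymocytes of wild-type (WT) mice and of mice homozygous for a knockout of DPASE (KO). Per the labels' protocols, thymocytes of mice aged 4 to 6 weeks were sorted as CD3e-negative DP cells, total RNA was extracted, and Tcra transcripts were amplified from their 5' ends by template-switch RACE with an antisense primer in the constant segment Trac. At steady state all preselection DP cells entered the library. At 24 h and 48 h after 1 mg of tamoxifen, the ZsGreen-positive cells were taken; per the labels, the mice carried TcrdCreER, a Cre recombinase activated by tamoxifen, and a ZsGreen reporter at Rosa26. The 3 samplings and 2 genotypes gave 6 groups of 2 libraries. The labels speak of groups of 2 mice and do not say whether each library came from its own mouse, so every p-value measures the spread between these libraries, which may be partly technical.

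The deposited values are fractions, per the file headers and the values: each table gives the fraction of the repertoire taken by each pair of a Trav and a Traj segment. The aligner, the genome build, the annotation of segments and whether the authors counted reads, molecules or clonotypes are not given in the sources used here. The sequencing depth in reads is therefore unknown, and no interval or detection limit was computed. The smallest fraction above 0 in a table marks its resolution. In 8 tables the fractions summed to between 0.995 and 0.998, the smallest share above 0 was 0.000348% to 0.00086%, and 1.18% to 14.3% of pairs stood at 0. In the other 4 tables, replicate 2 of both genotypes at 24 h and at 48 h, the fractions summed to between 1.97 and 1.99. Their smallest share was 0.00403% to 0.00956%, and 41.7% to 55.2% of pairs stood at 0. The deposited values below 2.5 times the smallest were multiples of 1 step in each of the 8 tables, 0.000335% to 0.00085%. In the other 4 they were steps of 2 sizes, 0.00793% to 0.0189%, or sums of these. If a step is 1 counted unit, its inverse is the number of units counted. The 4 tables then rest on far fewer units than the 8. No counts were restored from the steps.

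The tables share 79 of the 85 Trav segments listed in any of them, and all 43 Traj segments, which makes 3397 pairs. The 6 Trav segments listed in only some tables were left out of the tests. Each table was rescaled so that the 79 shared Trav segments sum to 100%, a choice made after the totals had been seen; these segments held 95.2% to 99.5% of the total in the 8 tables and 98.0% to 99.7% in the other 4. Pair shares were summed to a share per Traj and per Trav segment.

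The tests fixed before the data were examined were written for counts, with limma on log2(percent + 0.01) named as the test for fractions, and that test was used. A linear model with one mean per group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and 6 residual degrees of freedom. Benjamini-Hochberg adjustment at 0.05 was applied over the 43 Traj segments, the 79 Trav segments or the 3397 pairs. Fold changes are on the log2(percent + 0.01) scale, which understates the change of segments and pairs with low shares. The contrasts were KO minus WT at steady state, 24 h and 48 h, the mean of these 3 differences, 48 h minus 24 h in each genotype, and the difference of these changes between genotypes.

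For values with one number per library (mean Jα number, shares of windows and zones, diversity), an exact two-sided permutation test reassigned genotype within each sampling, over 216 arrangements, with the mean of the 3 KO minus WT differences as the statistic. Its smallest p is 0.00926. Within a single sampling, 2 libraries against 2 cannot go below 0.333, so no test was made there. For the change from 24 h to 48 h, time was permuted within genotype over 36 arrangements, and the smallest p is 0.0556. Adjustment ran over 27 such measures. Overall composition was compared with Bray-Curtis distances, as the mean distance between genotypes minus that within genotypes at the same sampling, in a one-sided test over the same 216 arrangements.

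The segment lists were fixed beforehand. Traj numbers fall from the 5' to the 3' end of the Jα array, and the lists were a 5' window (13 segments, Traj58 to Traj42), a middle window (16, Traj40 to Traj22), a 3' window (14, Traj21 to Traj2), the window of the TEA promoter (Traj58 to Traj53), that of the Traj49 promoter (Traj52 to Traj45) and the most 3' segments (Traj11 to Traj2). Trav segments were split by rank along the chromosome into zones distal (26), central (26) and proximal (27) to the Jα array. Further lists were Trav segments with the suffix d and the segments Trav16 to Trav21. Markers of other cells the gate could hold were the pair Trav11-Traj18 of invariant NKT cells and Trav1-Traj33 of MAIT cells. The dv-named segments, which can also rearrange in the Tcrd locus of gamma-delta cells, were listed beforehand as a further marker. Every pair joins a Traj and was amplified from Trac, so the dv-named share counts Tcra rearrangements only and cannot mark gamma-delta cells. No segment with the suffix n is in the tables analysed, and Traj61 was not analysed here. Segments named in the text are those past the threshold whose 2 KO libraries lie on the same side of both WT libraries, taken by size of change (6 per direction for KO against WT, 3 for pairs and for time), plus Traj58, Traj57, Traj56, Traj50, Traj49, Traj18, Traj33, Traj2, Trav1, Trav2, Trav11, Trav19, Trav21-dv12 and both marker pairs; others were chosen after their values were seen. Among these others are Traj segments named as calls of the replicate block alone, and the libraries overlap for Traj38 and Traj7 at 24 h, Traj28 at 48 h and Traj47, Traj44 and Traj31 in the mean of the 3. Coordinates are those of the GENCODE M21 annotation of GRCm38, a C57BL/6J genome. Per the labels, the Tcra-Tcrd locus of these mice came from strain 129, so coordinates give order and approximate distance. Of the 79 Trav segments, 77 are annotated there.

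The labels number the replicates 1 and 2 in every group. Libraries of the same number deviated together from their group means: across segments, the correlation of the WT with the KO deviations was 0.942, 0.662 and 0.406 for Traj and 0.723, 0.927 and 0.931 for Trav at steady state, 24 h and 48 h, and 0.462, 0.652 and 0.563 for pairs. Across 24 h and 48 h it was 0.509 in WT and 0.497 in KO for Traj, and 0.892 and 0.880 for Trav. The numbers were therefore treated as pairing the libraries. At 24 h and 48 h the number also parts the tables that sum to nearly 2 from the others. Shared deviations there cannot be told apart from how the tables were made. At steady state the numbers differ in the segments listed: Trav5-1 and Trav13d-2 only in replicate 2, Trav18 and Trav7-6 only in replicate 1. The correlations do not show that libraries of the same number were prepared together. The fit without the block, as fixed beforehand, gives the reported values. The value with replicate number within each sampling as a block (3 residual degrees of freedom) is given beside the calls and counts it affects most. That form of the block serves the KO minus WT contrasts. For the changes from 24 h to 48 h and their difference between genotypes, the block is a single term for replicate number. It is shared by all samplings, steady state included. The block for single values flips the signs of the 6 KO minus WT differences over 64 arrangements, with a smallest p of 0.0312.

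The limma step was tested on simulated log2 values with known changes, in 20 simulations per fold. Their noise was normal and independent between libraries, without zeros or a fixed total, and with 1 spread per segment for all groups. The recovery rates therefore leave out the pairing by number and the pairs at 0 in the real libraries. They also leave out the smaller spread of Trav shares at steady state, so the rate for Trav there does not describe those libraries. For the mean of the 3 differences, it recovered 91.2% of 8 Traj segments changed 1.5-fold and 98.1% of those changed 2-fold, 46.2% of 16 Trav segments changed 2-fold and 83.1% of those changed 4-fold, and 38.9% of 200 pairs changed 2-fold. At steady state it recovered 50.6% of Traj segments changed 1.5-fold and 83.8% of those changed 2-fold, and 5.31% of Trav segments changed 2-fold. Alternatives tried were pseudocounts of 0.001% and 0.1%, a filter on a mean share of 0.05%, fits to only the groups compared, the replicate block, leaving out each library, leaving out the 10 most abundant pairs, counting each pair above 0 once, other window borders and Jensen-Shannon distances. Added after the data had been examined were a centred log ratio, array weights, a term for the 4 tables that sum to nearly 2, fits without those tables, pairs of at least 0.01% only, and a denominator of all listed Trav segments. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.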

Results

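Tcra repertoires were profiled in preselection DP thymocytes, the cells in which Tcra rearranges before a receptor is selected. DPASE is, from general knowledge of the field, a regulatory element of the locus of Rag1 and Rag2, which encode the V(D)J recombinase. The series concerns RORγt, RAG expression and the Tcra repertoire. Successive rounds of rearrangement on one allele use Trav segments ever farther from the Jα array and Traj segments ever closer to its 3' end. The comparison of KO with WT mice therefore asks how usage along both arrays differs when DPASE is missing. The tamoxifen labelling asks the same of cells sampled 24 h and 48 h after labelling. There were 12 libraries, 2 each of WT and KO at steady state, at 24 h and at 48 h. The tables hold no value for DPASE, Rag1 or Rag2, so the genotype labels have no check in the data. Depth is unknown. The smallest share above 0 ranged from 0.000348% to 0.00086% in 8 libraries and from 0.00403% to 0.00956% in the 4 libraries of replicate 2 at 24 h and 48 h. In these 4, the deposited fractions summed to 1.97 to 1.99 in place of nearly 1. Their largest single pair held 0.801% to 1.35% of the repertoire against 0.239% to 0.678% in the other 8. On chromosome 14 of GRCm38, the annotated Trav segments tested lie between 52427928 and 53876752, from Trav1 to Trav21-dv12. The 43 Traj segments lie between 54157280 (Traj58) and 54217901 (Traj2), over 60.6 kb upstream of Trac. Values with ± are mean and SD of n = 2 libraries.

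At steady state, usage of the 3' end of the Jα array was lower in KO than in WT cells. Traj2, the most 3' segment tested (54217836 to 54217901), held 2.25% ± 0.147 of the WT and 0.345% ± 0.0330 of the KO repertoire, a log2 fold change of -2.67 (SE 0.18, adjusted p = 2.62e-06, limma). Traj4 fell by 1.68 on the log2 scale (SE 0.22, from 2.82% ± 0.385 to 0.871% ± 0.0939), Traj5 by 1.42, Traj6 by 1.21, Traj9 by 0.89 and Traj11 by 0.83. At the 5' side, Traj52 (54165316 to 54165381) rose from 2.70% ± 0.141 to 3.94% ± 0.238 (log2 fold change 0.55, SE 0.13, adjusted p = 0.0118). Traj50, Traj53 and Traj39 rose by log2 0.52, 0.47 and 0.45. Of the 13 segments of the 5' window, 3 rose and 10 were not called (3 adjusted over the list alone). Of the 16 of the middle window, 1 rose (0 adjusted over the list alone). Of the 14 of the 3' window, 7 fell and 7 were not called (7 adjusted over the list alone). Of the 4 segments of the TEA window, which follows the promoter that drives the first rearrangements, 1 rose (1 adjusted over the list alone). Of the 6 of the Traj49 window, 2 rose (4 adjusted over the list alone). Of the 7 most 3' segments, 6 fell (7 adjusted over the list alone). In all, 4 of 43 Traj segments rose and 7 fell, against 14 and 11 with the replicate block. The block called 11 of the 5', 3 of the middle and 11 of the 3' window, 3 of the TEA window and all 6 of the Traj49 window. Calls of the block alone include Traj57 (0.50, adjusted p = 0.0903 without and 0.00365 with it, limma), Traj49 (0.42, 0.0892 and 0.0118), Traj45 (0.48, 0.0567 and 0.00245), Traj7 (-1.07, 0.0953 and 0.00599), Traj42 (0.30, 0.0668 and 0.0243) and Traj56 (0.37, 0.186 and 0.014). Traj58 was called by neither (0.41, 0.236 and 0.117). A centred scale, in which each library is centred on the mean log share of its segments, was added after the data were examined. It moves the median over all 43 from 0.03 to 0.19, and on it 10 rose and 7 fell. The count of 11 was 5 without WT steady-state replicate 1, WT replicate 2 or KO replicate 1, 7 without KO replicate 2, and 17 without either KO library at 24 h. Traj50 and Traj39 each lost their calls without any one of the 4 steady-state libraries (adjusted p 0.0859 to 0.185 and 0.0586 to 0.206, limma). Traj52 and Traj11 lost theirs without WT replicate 1, WT replicate 2 or KO replicate 1 at steady state (up to 0.137 and 0.153). Traj53 lost its call without any of 6 libraries (up to 0.291).

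At 24 h, cells of both genotypes used mainly the 5' part of the array, and KO cells more so. Traj58 (54157280 to 54157342) held 3.38% ± 1.32 in WT and 6.59% ± 0.0835 in KO (log2 fold change 1.02, SE 0.26, adjusted p = 0.00576, limma). Traj57 held 4.84% ± 0.676 and 8.47% ± 1.97 (0.79, SE 0.20), and Traj56 held 6.47% ± 1.16 and 9.48% ± 2.40 (0.54, SE 0.21). The fold change of Traj58 was 0.61 without WT 24 h replicate 2 and 1.43 without WT 24 h replicate 1. Traj53, Traj52 and Traj50 rose by log2 0.51, 0.50 and 0.41. Middle and 3' segments fell. Traj30 fell from 1.63% ± 0.334 to 0.642% ± 0.274 (log2 fold change -1.38, SE 0.27, adjusted p = 0.00187), Traj27 by 1.24 on the log2 scale and Traj24 by 1.28. Traj2 fell by 1.77 (from 0.203% ± 0.0116 to 0.0526% ± 0.00898), Traj5 by 1.32 and Traj4 by 1.23. Of the 5' window, 6 of 13 rose (4 adjusted over the list alone), of the middle window 14 of 16 fell (14), and of the 3' window 10 of 14 fell (11). In the TEA window 4 of 4 rose (4 adjusted over the list alone), in the Traj49 window 2 of 6 (1), and 5 of 7 of the most 3' fell (5). In all, 6 of 43 rose and 24 fell, against 6 and 31 with the replicate block. The median over all 43 was -0.65 and moved to -0.12 on the centred scale, where 8 rose and 9 fell, among them 4 of the middle and 5 of the 3' window. Traj33 fell by 0.64 (SE 0.14), and Traj49 was not called (0.17, adjusted p = 0.371, limma). The 7 calls of the block alone were Traj18 (-0.68, adjusted p = 0.052 without and 0.00405 with it, limma), Traj42 (-0.24, 0.0724 and 0.0416), Traj11 (-0.49, 0.0579 and 0.0442), Traj43 (-0.36, 0.0606 and 0.0442), Traj40 (-0.27, 0.0734 and 0.0208), Traj38 (-0.90, 0.0612 and 0.00231) and Traj7 (-0.52, 0.306 and 0.048). Traj50 lost its call without any of 4 libraries (adjusted p 0.051 to 0.133, limma), the highest without WT 24 h replicate 2. Traj53 lost its call without WT 24 h replicate 1 (0.102) or KO 24 h replicate 2 (0.057), and Traj56 without these (fold change 0.35 and 0.28, adjusted p 0.206 and 0.271, limma) or any of 6 others. Traj27 fell by 0.82 without KO 24 h replicate 2.

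At 48 h, KO cells again had more of the 5' window and less of the 3' window. Traj52 rose from 2.56% ± 0.123 to 4.25% ± 0.00588 (log2 fold change 0.73, SE 0.13, adjusted p = 0.000825, limma). Traj42 rose from 3.18% ± 0.117 to 5.04% ± 0.174 (0.66, SE 0.11) and Traj45 from 2.70% ± 0.0669 to 4.54% ± 0.225 (0.75, SE 0.17). Traj50, Traj44 and Traj57 rose by log2 0.74, 0.70 and 0.61. Traj2 fell from 1.03% ± 0.169 to 0.163% ± 0.0306 (log2 fold change -2.59, SE 0.18, adjusted p = 3.46e-06). Traj9 fell from 1.86% ± 0.153 to 0.551% ± 0.0485 (-1.74, SE 0.15) and Traj11 from 0.888% ± 0.235 to 0.282% ± 0.00142 (-1.59, SE 0.21). Traj5, Traj4 and Traj6 fell by 1.97, 1.69 and 1.58 on the log2 scale. Of the 5' window 10 of 13 rose (10 adjusted over the list alone). Of the middle window 2 rose, 3 fell and 11 were not called (2 and 3), against 2 and 7 with the replicate block. On the centred scale 7 of the middle window rose and 2 fell, and its median moved from -0.02 to 0.33. Of the 3' window 13 of 14 fell (13). In the TEA window 2 of 4 rose (2 adjusted over the list alone), in the Traj49 window 5 of 6 (5), and 7 of 7 of the most 3' fell (7). In all, 12 of 43 rose and 16 fell, a count of 28 that was 18 without WT 48 h replicate 1. The replicate block called 14 and 21. On the centred scale 19 rose and 15 fell, and the median moved from -0.03 to 0.32. Traj49 rose by log2 0.53, and Traj58 (0.13, adjusted p = 0.688, limma) was not called. The 7 calls of the block alone were Traj56 (0.29, adjusted p = 0.235 without and 0.0237 with it, limma), Traj18 (-0.52, 0.125 and 0.0132), Traj47 (0.50, 0.129 and 0.0117), Traj30 (-0.53, 0.107 and 0.0086), Traj28 (-0.54, 0.253 and 0.000926), Traj27 (-0.47, 0.0974 and 0.016) and Traj26 (-0.37, 0.0946 and 0.00807). Traj44 lost its call without WT 48 h replicate 2 (fold change 0.45) or either KO 48 h library (adjusted p 0.0605 to 0.205, limma), and Traj57 without WT 48 h replicate 1 (0.128) or KO 48 h replicate 2 (0.131).

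Averaged over the 3 samplings, all 14 segments of the 3' window fell in KO cells (14 adjusted over the list alone; 12 on the centred scale) and 10 of the 13 of the 5' window rose (10; 13 on the centred scale). Traj2 fell by 2.35 on the log2 scale (SE 0.10, adjusted p = 5.52e-08, limma), Traj5 by 1.57, Traj4 by 1.53, Traj6 by 1.26, Traj9 by 1.23 and Traj12 by 1.03. Traj57 (0.63, SE 0.12), Traj52 (0.59, SE 0.07), Traj50 (0.55, SE 0.08), Traj53 (0.46, SE 0.09) and Traj56 (0.40, SE 0.12) rose, with KO above WT at every sampling. Traj58 (0.52, SE 0.15), Traj45 (0.45) and Traj49 (0.37, SE 0.10) rose as well. The replicate block alone called Traj44 (0.29, adjusted p = 0.0949 without and 0.00178 with it, limma), Traj47 (0.27, 0.137 and 0.0136), Traj31 (-0.18, 0.0615 and 0.0124) and Traj33. All 4 segments of the TEA window rose (4 adjusted over the list alone), 5 of 6 of the Traj49 window rose (5) and all 7 of the most 3' fell (7). In the middle window, 2 rose, 9 fell and 5 were not called (2 and 8 adjusted over the list alone). Its median of -0.20 turned to 0.14 on the centred scale, where 5 rose and 4 fell. Traj18, part of the invariant NKT chain, fell by 0.45 (SE 0.16, adjusted p = 0.0281, limma), a call lost without any of 5 libraries (0.0599 to 0.0773, the highest without WT 48 h replicate 1) and on the centred scale. Traj33, part of the MAIT chain, had -0.16 (adjusted p = 0.106, 0.0323 with the replicate block, limma), but 0.19 on the centred scale. In all, 12 of 43 rose and 23 fell, against 14 and 25 with the replicate block, and on the centred scale 18 rose and 16 fell (median -0.22 and 0.13). For 22 of 43 segments both KO libraries lay on the same side of both WT libraries at all 3 samplings, where chance gives 0.926%. For 6 more, Traj43, Traj42, Traj40, Traj39, Traj35 and Traj34, they lay above WT at steady state and 48 h and below it at 24 h (6 segments in mixed directions, where chance gives 2.78%). The lower side at 24 h depends on the scale, since on the centred scale all 6 had a positive fold change at 24 h (0.01 to 0.30).

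**Figure D1:**
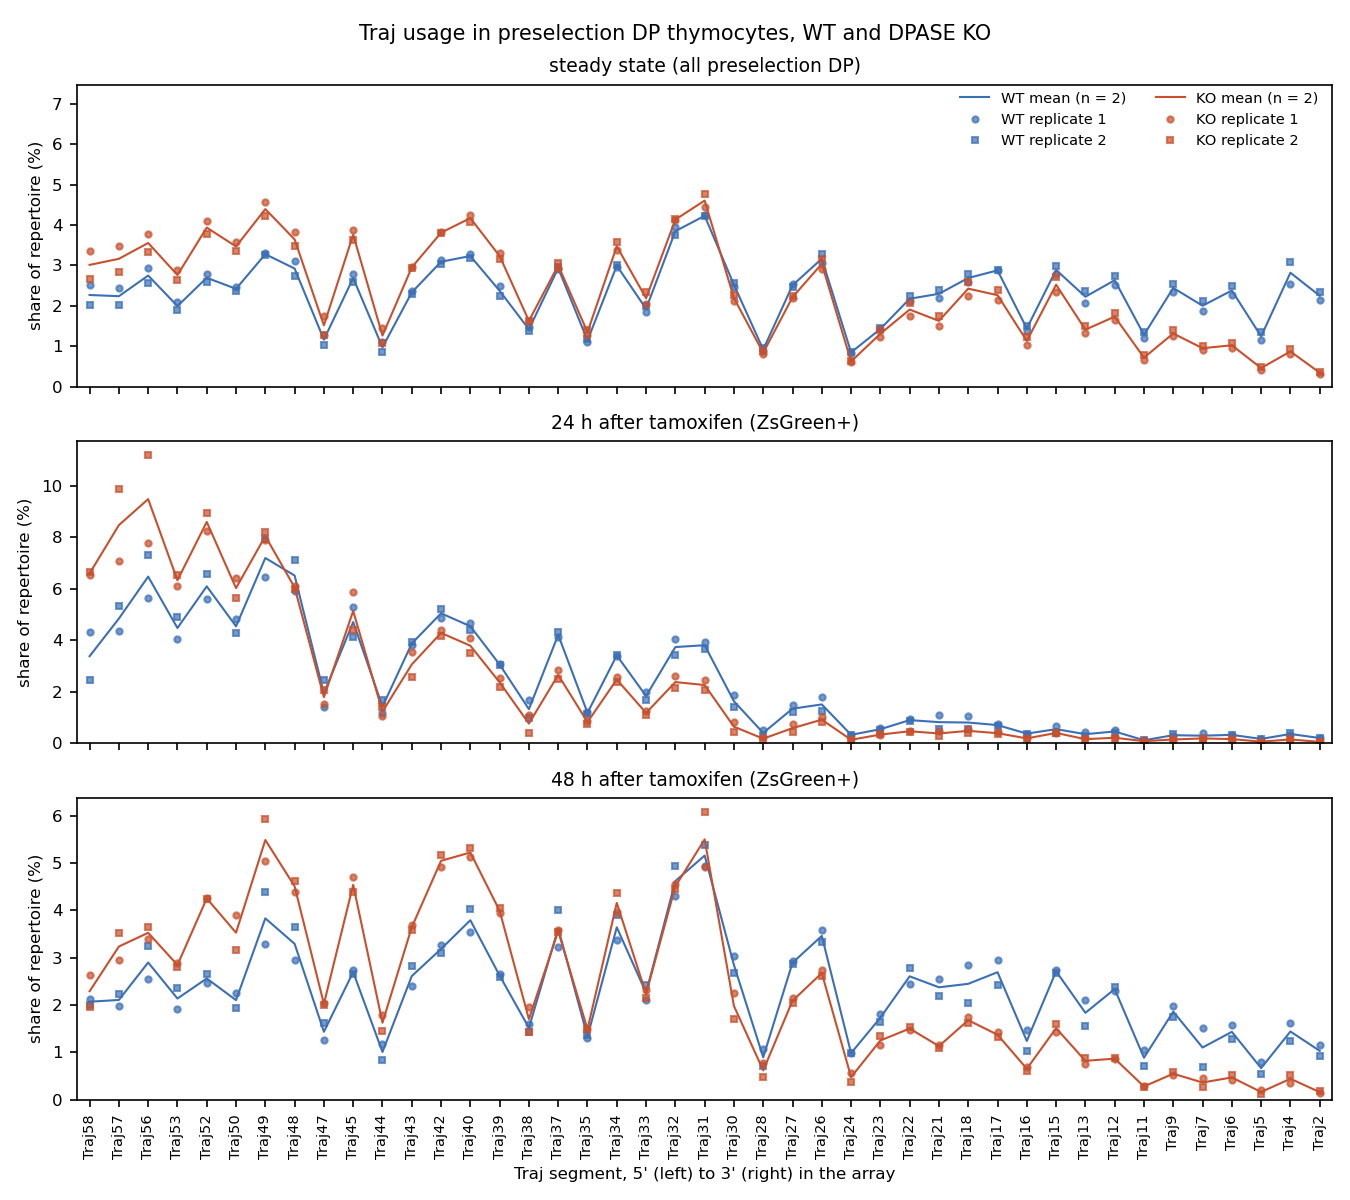
Share of the repertoire (percent) of each Traj segment along the Jα array, from Traj58 at the 5' end to Traj2 at the 3' end, in WT and KO libraries at steady state, 24 h and 48 h; points are libraries and lines are means of n = 2. At steady state and 48 h the KO means lie above the WT means in all 13 segments of the 5' window, and at 24 h in 8 of 13. At the 3' end Traj2 fell from 2.25% to 0.345% at steady state.

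The mean Jα number, weighted by usage (a higher number is closer to the 5' end), was higher in KO than in WT libraries in 6 of 6 pairs of the same number. It was 30.9 ± 0.933 in WT and 36 ± 1.00 in KO at steady state, 42.4 ± 0.888 and 46.4 ± 1.04 at 24 h, and 32.8 ± 1.24 and 38.5 ± 0.0280 at 48 h, a mean difference of 4.95 segment numbers (exact permutation p = 0.00926, the smallest possible, adjusted 0.0167). The 5' window held 30.8% ± 2.17 and 41.3% ± 3.10 at steady state, 60.5% ± 3.89 and 75% ± 3.57 at 24 h, and 31.9% ± 2.20 and 46.5% ± 0.0835 at 48 h, a mean difference of 13.2 percentage points. The most 3' segments, Traj11 to Traj2, held 14.4% ± 1.23 and 5.68% ± 0.540 at steady state, 1.77% ± 0.0690 and 0.831% ± 0.0341 at 24 h, and 8.43% ± 1.81 and 2.45% ± 0.0938 at 48 h. The whole 3' window held 31.5% ± 2.11 and 18.8% ± 1.80, 5.82% ± 1.22 and 3.04% ± 0.435, and 24.1% ± 3.69 and 10.5% ± 0.0371. The TEA window rose from 9.26% ± 1.06 to 12.5% ± 1.43, from 19.2% ± 1.13 to 30.9% ± 4.76 and from 9.21% ± 0.901 to 11.9% ± 0.0404. The Traj49 window was 6.21 points higher on average. These 5 shares gave the same exact permutation p of 0.00926 (adjusted 0.0167) with 6 of 6 pairs in one direction. The middle window differed by -3.52 points (p = 0.25, exact permutation, adjusted 0.321, with 3 of 6 pairs in that direction). Across the 43 segments, which are not independent, the log2 fold change was lower with distance from Traj58. Spearman's rho was -0.961, -0.817 and -0.922, with slopes of -0.34, -0.31 and -0.47 per 10 kb at steady state, 24 h and 48 h. The last Traj with a positive fold change was Traj31 at steady state and 48 h and Traj45 at 24 h. This point depends on the scale: on the centred scale it was Traj18 at steady state, Traj7 at 24 h and Traj31 at 48 h, with 26, 20 and 22 segments positive.

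**Figure D2:**
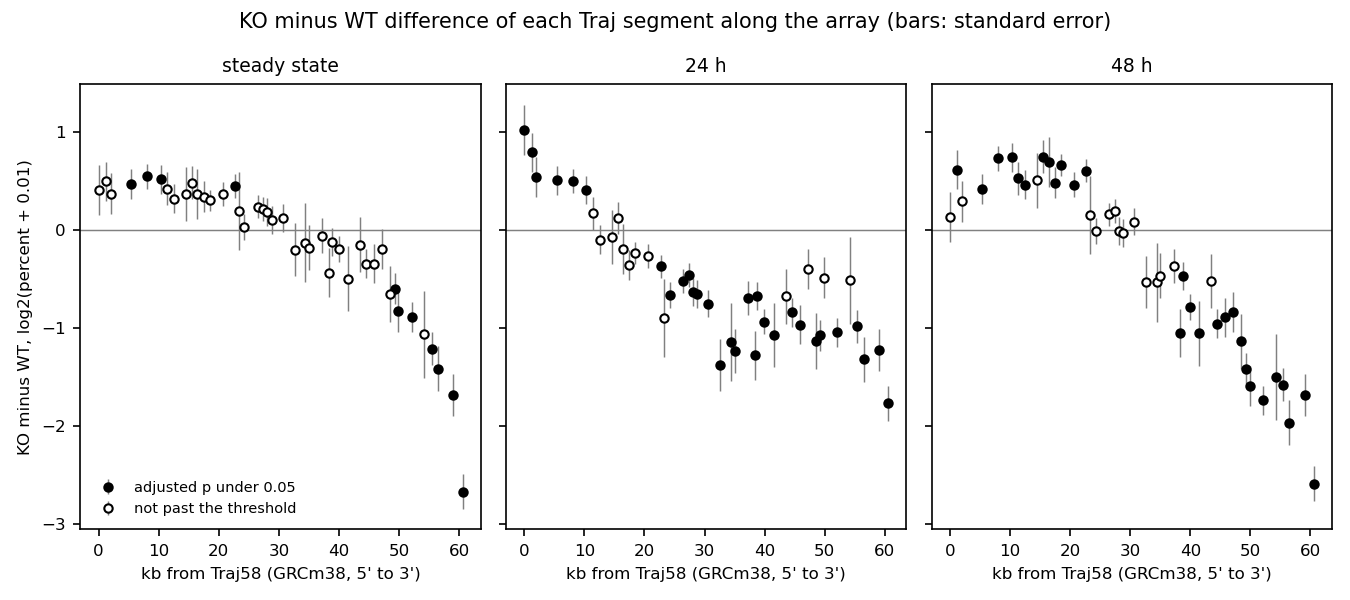
Log2 fold change of Traj usage, KO minus WT, against distance from Traj58 (kb, GRCm38) at steady state, 24 h and 48 h; each point is a segment, bars are SE, and filled points have an adjusted p under 0.05 (limma). The fold change falls along the array, with slopes of -0.34, -0.31 and -0.47 per 10 kb.

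On the Vα side, KO cells had less of the Trav segments far from the Jα array and more of those close to it. The distal zone (Trav1 to Trav12d-3) held 28.7% ± 1.09 in WT and 22% ± 0.922 in KO at steady state, 14.9% ± 0.892 and 13.9% ± 0.267 at 24 h, and 23% ± 4.97 and 17.4% ± 1.62 at 48 h, a mean difference of -4.41 points (exact permutation p = 0.00926, adjusted 0.0167, 6 of 6 pairs). The proximal zone (Trav13-1 to Trav21-dv12) held 36% ± 2.93 and 43.7% ± 2.56, 61.7% ± 4.88 and 65.0% ± 2.06, and 43.3% ± 8.70 and 53.5% ± 5.39, a mean difference of 7.06 points (exact permutation p = 0.0278, adjusted 0.0441, 6 of 6 pairs). The mean Vα rank, counted from Trav1 as 1, was 41.1 ± 1.06 and 45.3 ± 0.987, 52.8 ± 1.58 and 54.1 ± 0.115, and 44.1 ± 2.94 and 48.8 ± 1.65, a mean difference of 3.42 ranks (exact permutation p = 0.00926, adjusted 0.0167). The central zone differed by -2.65 points (adjusted 0.211 by exact permutation, 0.0469 with the replicate block), and by -1.70 without WT 24 h replicate 1 or -1.76 without KO 48 h replicate 2. Segments with the suffix d differed by -5.47 points (adjusted exact permutation p = 0.0441, 0.0804 with the block, 5 of 6 pairs). Trav16 to Trav21 differed by 1.49 points (adjusted exact permutation p = 0.341, 0.0469 with the block, 6 of 6 pairs). This was 0.432 or 2.54 without KO 24 h replicate 1 or 2, 2.25 or 0.726 without WT 24 h replicate 1 or 2, and 0.908 without KO 48 h replicate 1. The call of the rank was lost without WT 48 h replicate 1 (2.72, adjusted exact permutation p = 0.0625) or KO 48 h replicate 2 (3.03, 0.0667). That of the distal share was lost without these (-3.24 and -4.03) or KO 48 h replicate 1 (-4.79), and that of the suffix d share without KO 24 h replicate 1 (-5.00, and at 24 h 0.186 in place of -1.24) or any of 3 libraries at 48 h. That of the proximal share was lost without any of 7 libraries (5.01 without WT 48 h replicate 1), and without WT 24 h replicate 1 its difference at 24 h was -0.145 points. Without WT replicate 1 or 2, the distal difference was -0.347 or -1.61 at 24 h and -2.04 or -9.06 at 48 h, and that of the rank 0.257 or 2.48 at 24 h. The proximal difference was 6.76 without WT replicate 2 and 1.85 without KO replicate 2 at 24 h. At 48 h it was 4.01 or 16.3 without WT replicate 1 or 2 and 6.35 without KO replicate 2, and the rank difference was 2.66 without WT replicate 1.

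No single Trav segment passed the threshold without the block. Limma called 0 of 79 at steady state, 24 h, 48 h and in the mean of the 3, with 0, 0, 1 and 4 at an unadjusted p under 0.05. The fit shares 1 spread over all samplings. The median deviation of Trav libraries from their group mean was 0.078 on the log2 scale at steady state and 0.498 at 24 h and 48 h. The absence of calls at steady state is therefore weak evidence. Both KO libraries lay on the same side of both WT libraries for 55, 10 and 16 of 79 segments at the 3 samplings, where chance gives 33.3%. None of the Vα lists had a call (0 adjusted over the list alone). With the replicate block, 0, 4, 28 and 36 were called. In the mean of the 3 with the block, 13 of 26 distal segments fell, 1 central segment rose and 9 fell (0 and 2 adjusted over the list alone), and 13 of 27 proximal segments rose. Adjusted over the list alone, the distal and proximal counts were 13 and 14. By the other lists, 17 of 33 suffix d segments fell, 4 of the 5 from Trav16 to Trav21 rose, and 2 of 10 dv-named segments rose and 3 fell. Trav1, the most distal segment (52427928 to 52428876), held 2.03% ± 0.349 and 1.05% ± 0.272 at steady state, 0.0504% ± 0.0419 and 0.0374% ± 0.0113 at 24 h, and 0.922% ± 0.568 and 0.249% ± 0.121 at 48 h. Its fold change was not called without the block (mean log2 fold change -0.97, adjusted p = 0.703 without and 0.0138 with the replicate block, limma). Trav17 (53806639 to 53807115) held 0.938% and 1.33%, 1.81% and 2.77%, and 0.797% and 1.34% (0.62, adjusted p = 0.703 and 0.00482 with the block). Trav4d-4 held 1.55% and 1.21%, 0.571% and 0.358%, and 1.37% and 0.816% (-0.59, 0.00482 with the block). At 48 h the block also called Trav3-4 (0.96), Trav4-4-dv10 (0.80), Trav17 (0.74), Trav9-4 (0.69), Trav9-3 (0.67), Trav12-2 (0.54), Trav1 (-1.79), Trav4d-4 (-0.74), Trav13d-1 (-0.51) and Trav19 (0.78), and at 24 h Trav6-2 (-1.06), Trav4d-4 (-0.68) and Trav17 (0.61). In the mean of the 3, Trav12-1 had 0.44 and Trav14d-3-dv8 -0.21 (0.0411 each with the block). Trav19 and Trav21-dv12, at the proximal end of the Trav segments tested, had 0.40 and 0.28 (adjusted p = 0.94 each, 0.0422 and 0.0369 with the block, limma), and Trav11 had -0.26 (0.94, 0.143 with the block). Leaving out 1 library moved Trav19 from 0.10 (WT 48 h replicate 2) to 0.70 (WT 48 h replicate 1), and by over 1.5 times for 7 of the 8 libraries at 24 h and 48 h, all but WT 24 h replicate 1. It moved Trav21-dv12 from 0.04 (KO 48 h replicate 1) to 0.51 (KO 48 h replicate 2), and by over 1.5 times for all 8. All 26 distal segments had a negative mean fold change, 25 of them also on the centred scale, and 24 of 27 proximal segments a positive one.

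**Figure D3:**
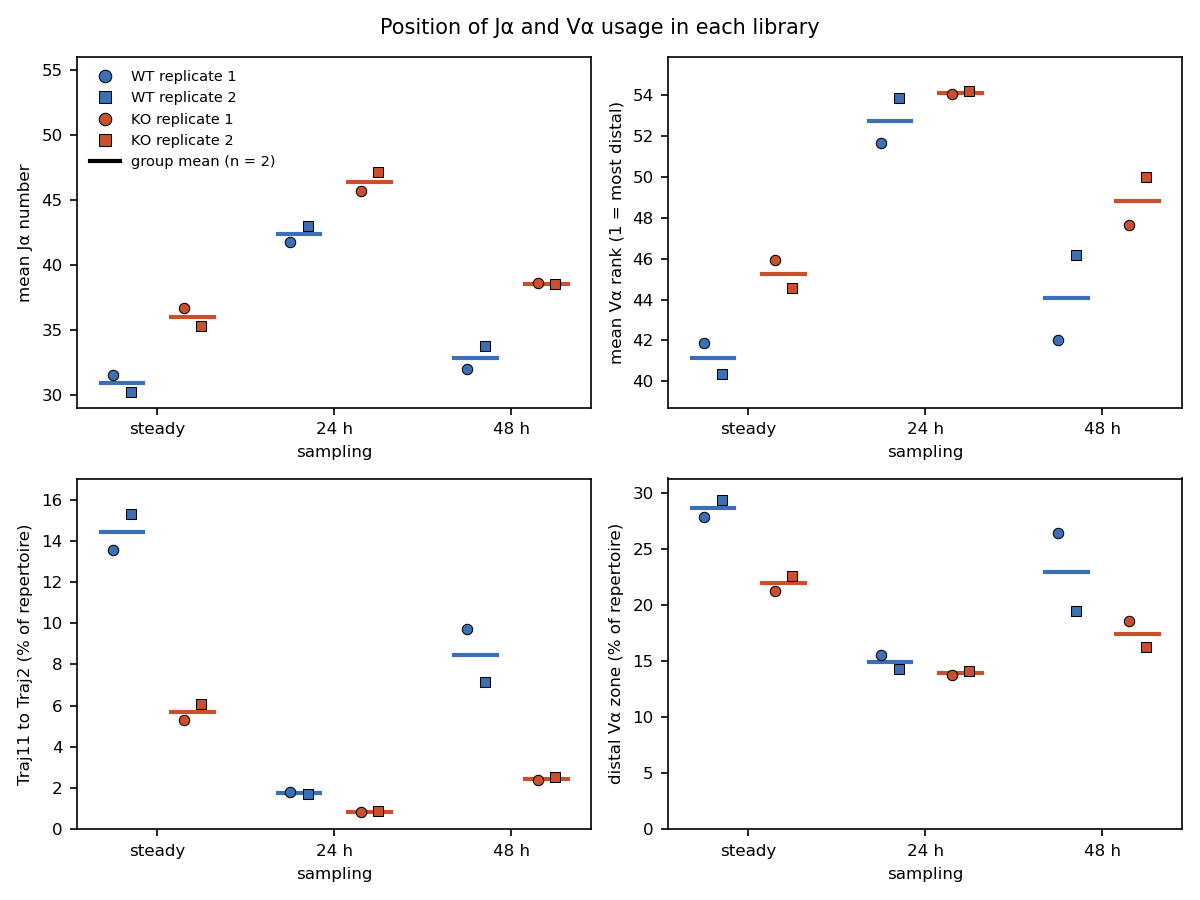
Mean Jα number, mean Vα rank, share of Traj11 to Traj2 (percent) and share of the distal Vα zone (percent) in each library, by genotype and sampling; points are libraries and bars are means of n = 2. The KO libraries lie above the WT libraries in mean Jα number and below them in the share of Traj11 to Traj2 at every sampling.

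Combining both arrays, the share of distal Trav with 3' Traj was lower and that of proximal Trav with 5' Traj higher in KO at every sampling. Distal Trav with 3' Traj held 12.9% ± 1.39 in WT and 5.85% ± 0.785 in KO at steady state, 0.943% ± 0.234 and 0.432% ± 0.0605 at 24 h, and 7.19% ± 2.77 and 2.14% ± 0.128 at 48 h. Proximal Trav with 5' Traj held 17.3% ± 1.51 and 23.6% ± 2.26, 39.0% ± 4.73 and 49.3% ± 3.33, and 19.5% ± 3.86 and 28.7% ± 2.72. The mean differences were -4.22 and 8.59 points. They were -3.96 for central and -1.51 for proximal Trav with 3' Traj, 1.79 for distal and 2.83 for central Trav with 5' Traj, and -1.99 for distal Trav with middle Traj. Each had an exact permutation p of 0.00926 (adjusted 0.0167, 6 of 6 pairs). Central and proximal Trav with middle Traj differed by -1.51 (adjusted 0.275) and -0.0252 points (0.981), by exact permutation. Without 1 library, the central difference ranged from -2.12 to -0.911 points. Without KO 48 h replicate 1 or 2, the distal and 3' block had an adjusted p of 0.05 or 0.0667 by exact permutation.

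All pairs that fell without the block joined a Traj of the 3' window, 10 of 10 at steady state and 36 of 36 in the mean of the 3, while 32.6% of all pairs do. No test was made of this. At steady state Trav13d-1 with Traj2 fell from 0.0879% ± 0.0172 to 0.00844% ± 0.00377 (log2 fold change -2.41, SE 0.29, adjusted p = 0.0339, limma, and 0.0845 with the replicate block). Trav7-4 and Trav7d-4 with Traj2 fell by 1.89 and 1.87 on the log2 scale (0.128 and 0.0845 with the block). Of 3397 pairs, 10 fell and 0 rose, with 212 at an unadjusted p under 0.05. The replicate block called 0 (335 unadjusted). At 24 h and 48 h limma called 0 pairs (188 and 511 unadjusted). The block called 0 (462 unadjusted) and 56, all lower and 52 of them with a 3' Traj, among them Trav7-4 with Traj2 (-2.33), Trav7d-3 with Traj9 (-2.11) and Trav1 with Traj17 (-2.10). In the mean of the 3, 36 fell, with 539 at an unadjusted p under 0.05, and the block called 76, 72 lower and 4 higher, 29 of them shared. Trav7-4 with Traj2 fell by 1.80 (SE 0.16, adjusted p = 0.00977), Trav13d-1 with Traj4 by 1.54 and Trav4d-3 with Traj2 by 1.37. Trav17 with Traj52 (0.87) and Trav3d-3 with Traj50 (0.83) rose with the block. The count of 10 was 0 without any of 10 libraries and 95 without either WT library at 48 h. The count of 36 was 0 without any of 6 libraries, among them all KO libraries at steady state and 24 h, and 292 without WT 48 h replicate 2. The named pairs lost their calls with these libraries.

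From 24 h to 48 h after labelling, usage moved toward the 3' end in both genotypes. In WT cells Traj11 rose from 0.115% ± 0.0102 to 0.888% ± 0.235 (log2 fold change 2.82, SE 0.21, adjusted p = 2.22e-06, limma), Traj9 by log2 2.55 and Traj13 by 2.37. Traj52 fell from 6.09% ± 0.671 to 2.56% ± 0.123 (-1.24, SE 0.13), Traj57 by 1.19 and Traj56 by 1.15. In KO cells Traj13 rose by log2 2.37, Traj12 by 2.00 (from 0.213% ± 0.0427 to 0.870% ± 0.00695) and Traj15 by 1.89, and Traj58, Traj56 and Traj57 fell by 1.54, 1.40 and 1.37. Of the 5' window 11 of 13 fell in WT and 8 in KO, and of the 3' window 14 of 14 and 13 of 14 rose, with the same counts adjusted over the list alone. Of the middle window 8 of 16 rose in WT, with a median of 0.37 that turned to -0.28 on the centred scale (5 up, 7 down). In KO 16 of 16 rose (8 up, 2 down on the centred scale). In all, 22 rose and 11 fell in WT and 29 and 8 in KO. On the centred scale 19 rose and 20 fell in WT and 20 and 13 in KO, and the medians moved from 0.44 to -0.22 and from 1.27 to 0.43. The mean Jα number changed by -9.55 in WT and -7.84 in KO (exact permutation p = 0.0556 for the mean change, the smallest possible, adjusted 0.075). These changes differed by 1.71 (exact permutation p = 0.667), and by 0.835 or 2.58 without WT 48 h replicate 1 or 2, 1.08 without WT 24 h replicate 2 and 0.977 without KO 24 h replicate 1. The mean Vα rank changed by -8.67 and -5.30.

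Among Trav segments, Trav1 rose from 24 h to 48 h in WT cells (log2 fold change 4.00, SE 0.65, adjusted p = 0.0194, limma), from 0.0504% to 0.922%. Trav9d-4 rose in KO cells from 0.0991% ± 0.0152 to 0.470% ± 0.130 (2.12, SE 0.39, adjusted p = 0.0439, limma). The call of Trav1 was lost without WT 24 h replicate 2 (3.22, adjusted p = 0.15), WT 48 h replicate 1 or either WT steady-state library, and that of Trav9d-4 without any of 10 libraries (0.404 without KO 48 h replicate 1). These were the single calls of 79, with 13 and 11 at an unadjusted p under 0.05. The block called 7 and 5, among them Trav7-2 (1.89), Trav6-2 (1.72), Trav3-4 (-1.64), Trav17 (-1.16) and Trav8-2 (-1.06) in WT and Trav1 (2.38), Trav7-1 (2.30), Trav6-2 (2.25) and Trav17 (-1.03) in KO. Of pairs, 206 rose and 28 fell in WT (362 in all with the block). The largest changes were those of Trav12d-2 with Traj18 (3.11), Trav10 with Traj13 (2.61, or 1.48 without WT 48 h replicate 2) and Trav13d-1 with Traj6 (2.57) and of Trav3-4 with Traj53 (-2.40), Traj52 (-2.11) and Traj49 (-2.10), and each lost its call without 7 to 10 of the libraries. Limma called 0 pairs in KO (631 unadjusted). The WT count was 0 without WT 24 h replicate 2 or any of the 4 steady-state libraries. The change with time differed between genotypes for 13 Traj segments (0 in a fit to only the 4 groups compared, 14 unadjusted), 0 Trav segments (1 at an unadjusted p under 0.05) and 0 pairs (287 unadjusted) by limma.

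The Traj composition differed between genotypes more than within them: the mean Bray-Curtis distance was larger by 0.104 between genotypes (exact permutation p = 0.037, one-sided). That p is the smallest possible here, since exchanging WT and KO within a sampling leaves the statistic unchanged. For Trav and for pairs the difference was -0.0584 and -0.0113 (exact permutation p = 0.593 each). This test leaves the pairing by number aside, and the distance within a genotype is that between replicates 1 and 2. Between WT and KO of the same number the distance was 0.113 for Trav and 0.236 for pairs, against 0.251 and 0.310 within genotypes, so the negative values reflect the pairing and do not show that genotypes are alike. Shannon diversity of pairs differed by -0.230 bits (exact permutation p = 0.343, adjusted 0.385), from -0.0376 without WT 48 h replicate 1 to -0.423 without WT 48 h replicate 2, and the number of pairs above 0 by -121 (p = 0.611, exact permutation), in tables of unequal resolution. The 2 marker pairs and the dv-named share did not pass the threshold in the exact permutation test over the 3 samplings. Trav11-Traj18 held 0.0420% ± 0.00916 in WT and 0.0428% ± 0.00644 in KO at steady state (mean difference -0.00815 points, exact permutation p = 0.343). Without 1 library that difference ranged from -0.0139 to -0.00236 points. Trav1-Traj33 held 0.0474% ± 0.00775 and 0.0374% ± 0.0101 at steady state (-0.0115 points, p = 0.0556, exact permutation, adjusted 0.0833). The dv-named Trav segments held 12% ± 0.642 and 12.8% ± 0.846 (-0.127 points, exact permutation p = 0.981). At 48 h WT and KO had 0.0372% ± 0.0119 and 0.0174% ± 0.0246 for Trav11-Traj18, 0.0288% ± 0.0134 and 0.00641% ± 0.00907 for Trav1-Traj33, and 23.1% ± 15.2 and 19.4% ± 8.64 for the dv-named segments. In replicate 1 at 48 h, WT and KO had 0.0456% and 0.0347% for Trav11-Traj18 and 0.0383% and 0.0128% for Trav1-Traj33. KO replicate 2 at 48 h had 0 for both pairs, in a library with 44.3% of all pairs at 0. The dv-named means rest on replicate 2, with 33.9% and 25.6% against 12.4% and 13.3% in replicate 1. Trav15-2-dv6-2, named after its values were seen, held 18.7% and 11.7% there against 0.566% and 0.672%. The dv-named share counts Tcra pairs only, so neither these means nor its test can tell whether gamma-delta cells were present.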

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

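The tests of summed tables, of lower depth alone, of Trav copies as the whole cause, of the weights, of abundant pairs, of the pairs of tables outside the set and of reassigned genotypes were chosen after the results were seen. Those of the Trav copies by medians and of the mixture by its residual were written before, and the medians were restricted to subgroups with copies after.

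The change from 24 h to 48 h differed between genotypes for 13 Traj segments, 10 of them gaining in KO relative to WT. Traj39 had a KO minus WT fold change of -0.37 at 24 h and 0.60 at 48 h (0.16 and 0.96 on the centred scale, so the sign at 24 h depends on the scale), a difference of 0.98 on the log2 scale (SE 0.17, adjusted p = 0.00482, limma), and Traj42 had 0.90 (SE 0.16). The others that gained were Traj43 (0.84), Traj31 (0.84), Traj40 (0.73), Traj35 (0.68), Traj34 (0.65), Traj37 (0.65), Traj33 (0.62) and Traj32 (0.62). Traj9 (-0.69), Traj2 (-0.82) and Traj11 (-1.11, SE 0.29) moved the other way. By list, 2 of 13 of the 5' window and 8 of 16 of the middle window rose, and 3 of 14 of the 3' window fell. On the centred scale 3 of 43 were called, and a fit to only the 4 groups compared, fixed before, called 0 by limma (14 at an unadjusted p under 0.05). With the replicate block Traj33 lost its call (adjusted p = 0.0508, limma), and Traj58 (-0.89, 0.0878 without and 0.0331 with it) and Traj45 (0.63, 0.0734 and 0.0355) gained one. The count of 13 was 2 without KO 24 h replicate 2, KO 48 h replicate 2 or WT 48 h replicate 1, and 18 without KO 24 h replicate 1. All but Traj39 and Traj42 lost their calls without 3 to 9 of the libraries (adjusted p up to 0.134).

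A lag along the same path could make KO usage at 48 h a single mixture of WT usage at 24 h and at 48 h, and the residual of the best mixture does not decide this. It was 2.06 and 2.57 times the difference between the WT steady-state replicates for the numbers 1 and 2, past the bound of 2 written before, but steady-state libraries are no part of the mixture. At 0.445 and 0.556 the residuals exceed the difference between the KO libraries at 48 h (0.342) and that between the WT libraries at 48 h (0.435), and lie below that between the WT libraries at 24 h (0.647). The weights argue against a single mixture: over the 8 combinations of the 6 libraries, the weight of WT usage at 24 h was 0.200 to 0.342 for the TEA share and 0.855 to 0.929 for Traj11 to Traj2, a difference of 0.570 to 0.680. A path through a time not sampled, or a difference between genotypes in the sorted gate or in cell age, was not tested and stays open.

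The Jα shift does not rest on the 4 tables that sum to nearly 2 or on a few abundant pairs. Outside these tables the smallest difference in mean Jα number was 3.90, and without the 10 most abundant pairs the mean difference was 4.99. When genotypes were reassigned within samplings, 1 of 100 splits, the real one, reached 35 Traj calls (the highest other had 25), and with the replicate block 1 of 32 reached 39 (33). For Trav 100 of 100 reached the real count of 0 and 1 of 32 reached 36 with the block (12). For pairs 7 of 100 reached 36 and 1 of 32 reached 76 with the block (0). The highest other counts without the block, 54 for Trav and 731 for pairs, came from splits that parted 0 and 2 of the 6 pairs of the same number. The split for Trav thus set replicate 1 against replicate 2 at every sampling. Whether the count of 731 follows the difference between tables was not tested.

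The 4 tables, replicate 2 at 24 h and 48 h in both genotypes, are likely sums of 2 tables of fractions each. In all 4, 100% of the values below 2.5 steps are steps of 2 sizes or sums of these, within 1.1 units of the third digit, where evenly spread values would match at 3.55% to 8.33%; 1 step size matches 18.7% to 21.6%, against 100% in the other 8 tables. Lower depth alone would leave deviations unrelated between genotypes, but these correlated at 0.927 or more over Trav segments. A shift of reads between near-identical Trav copies leaves the sum over a subgroup as it was, but in 8 of the 14 subgroups with copies (2 above, 6 below) the summed share lay outside the range of the other 8 tables in all 4, so it is not the whole cause; summing over these copies left 0.648 of the deviation of single segments, between the bounds of 1/3 and 2/3 written before, so a shift between copies as a part of it stays open.

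Trav18 and Trav7-6, left out of the tests because only some tables list them, were higher in KO in 2 of 2 pairs of tables each (0.0207% in WT and 0.0280% in KO, and 0.0231% and 0.0410%).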

How the results depend on the processing

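The alternatives named as added, among them the centred scale, were chosen after the result was seen, and the others were fixed before the data were examined.

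The limits are those of 12 libraries of unknown depth in reads, 2 per group, of which 4 are likely sums of 2 tables. In these 4, 100% of the values below 2.5 steps match 2 step sizes within rounding. Evenly spread values would match at 3.55% to 8.33%. TMM, DESeq2, thinning to equal depth, filters on 2 or 10 counts, segments under 10 counts and a log ratio with 0.5 counts were not run. They need counts, which are not given and were not restored from the steps. Of the segment values under the alternatives fixed before, other than leaving out a library, 385 stayed the same in direction and side of the threshold, 47 were weaker and 4 stronger. Of the summary values under these alternatives, 165 stayed the same, 18 were weaker, 2 stronger and 7 reversed. Of the counts of calls, 74 stayed near the reported count and 28 moved. Leaving out 1 library turned the direction of 4 segment values and 18 summary values, and ended calls as given with the results. For the changed values below the cause was not tested.

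Pairing by replicate number (the replicate block) gave 25 Traj segments at steady state, 4 Trav segments at 24 h, 28 at 48 h, 36 in the mean of 3, 7 for WT and 5 for KO from 24 h to 48 h. For pairs it gave 0 at steady state, 56 at 48 h, 76 in the mean of 3 and 362 for WT over time, and the central share (-2.65) passed the threshold. The calls of named segments, pairs and shares that it affected most are given with the results.

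Counting each pair above 0 once can register almost no shift in usage where nearly all of the 3397 pairs are above 0. At steady state 3345 to 3347 were, and in replicate 1 at 48 h 3357 in WT and 3301 in KO. No conclusion is drawn from the smaller differences or turned signs that this setting gave. The differences were 1.32 for mean Jα number, 3.19 for the 5' share, -2.86 for the 3' share and 1.12 for the TEA share. They were 1.48 for the Traj49 window, -1.83 for the most 3' share, 0.742 for mean Vα rank, -1.24 for the distal share and 1.37 for the proximal share. The blocks were 0.650, -0.513 and -1.37 for distal Trav with 5', middle and 3' Traj, 1.21 and -1.08 for central Trav with 5' and 3' Traj, and 1.33 and -0.415 for proximal Trav with 5' and 3' Traj. The sign turned for the dv-named share (0.361), proximal Trav with middle Traj (0.458), the difference of the time changes in mean Jα number (-0.865) and the middle share at 48 h (0.748). Proximal Trav with middle Traj also turned without the 10 most abundant pairs (0.0347), with other window borders (1.57), with pairs of at least 0.01% only (0.0188) and without the 4 summed tables (0.764). So did the middle share at 48 h with other borders (5.92) and without the 4 tables (0.00723), and the dv-named share without them (0.634).

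Of the added settings, array weights gave 24 Traj segments at steady state, 0 Trav segments for KO over time, and 477, 4 and 0 pairs at steady state, in the mean of 3 and for WT over time. The centred scale gave 17 Traj segments at steady state, 17 at 24 h and 3 for the difference of changes, 6 Trav segments over time in WT and 6 in KO, 1 pair at steady state and 7 in the mean of 3, and Traj33 turned to 0.19. A term for the 4 summed tables gave 19 Traj segments at steady state and 24 for the difference of changes, and 1, 11, 28, 47 and 36 Trav segments at 24 h, at 48 h, in the mean of 3 and over time in WT and KO. For pairs it gave 180 at 48 h, 226 in the mean of 3, 790 for WT and 441 for KO over time. Leaving out the 4 tables leaves 1 library in each group at 24 h and 48 h. The spread in that fit comes from the steady-state libraries alone. Its counts other than those at steady state rest on single libraries judged by that spread. They cannot tell a difference between groups from one between libraries, and no conclusion is drawn from them. Without the 4 tables there were 28 Traj segments at steady state and 23 for the difference of changes, 26, 49 and 29 Trav segments in the mean of 3 and over time in WT and KO, and 357, 650, 1242, 1619 and 1239 pairs at steady state, at 48 h, in the mean of 3 and over time in WT and KO.

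Of the settings fixed before, a fit to only the groups compared gave 28 Traj segments at steady state and 0 for the difference of changes, 0 Trav segments over time in WT and in KO, 357 pairs at steady state and 0 for WT over time. A filter on 0.05% gave 0 pairs at steady state, in the mean of 3 and for WT over time, and 1 for KO over time. A pseudocount of 0.001% gave 0 pairs at steady state, 2 in the mean of 3 and 0 for WT over time. A pseudocount of 0.1% gave 0 Trav segments for KO over time, and 60, 25, 95 and 62 pairs at steady state, at 48 h, in the mean of 3 and for KO over time.

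Leaving out each library in turn gave 5 to 17 Traj segments at steady state, 18 to 30 at 48 h and 2 to 18 for the difference of changes, and 0 to 1 Trav segments over time in WT and in KO. For pairs it gave 0 to 95 at steady state, 0 to 1 at 24 h, 0 to 248 at 48 h, 0 to 292 in the mean of 3, 0 to 415 for WT and 0 to 86 for KO over time, and 0 to 3 for the difference of changes. The mean Vα rank ranged from 2.72 to 4.11, the distal share from -5.58 to -3.24, the proximal share from 5.01 to 9.11 (at 24 h from -0.145 to 6.76) and distal Trav with 3' Traj from -4.87 to -3.57. Values near 0 changed sign: the dv-named share (-3.72 to 3.46), proximal Trav with middle Traj (-0.970 to 0.919), the middle share at 48 h (-2.07 to 0.0400), the number of pairs above 0 (-369 to 126) and Trav11 (-0.74 to 0.22).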

Other observations

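The test of the Vα shift by standardisation was written before the result was seen, and the Jα means by Vα zone, the effective number of Traj segments and the other tests of the Vα shift were chosen after.

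The Jα shift was present within every Vα zone. Among distal Trav segments the mean Jα number was 25.7 ± 1.17 in WT and 32.6 ± 1.20 in KO at steady state, 42.4 ± 0.915 and 47.2 ± 1.14 at 24 h, and 29.4 ± 1.13 and 37.2 ± 0.352 at 48 h. The mean difference was 6.50 for distal, 5.22 for central and 3.02 for proximal segments, each with 6 of 6 pairs in one direction (exact permutation p = 0.00926, the smallest possible). The difference between zones was not tested. KO cells also spread their usage over fewer Traj segments: the effective number fell from 40.5 ± 0.0331 to 37.2 ± 0.568 at steady state, from 28.3 ± 1.66 to 22.4 ± 1.74 at 24 h and from 38.8 ± 1.37 to 33 ± 0.702 at 48 h (exact permutation p = 0.00926).

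Among the Trav segments left out of the tests, Trav2 was lower in KO in 5 of 5 pairs of tables (0.923% in WT and 0.474% in KO, means over 5 tables pooled across the samplings). Trav5-1 and Trav13d-2 were lower in 4 of 4 pairs (0.845% and 0.504%, and 0.503% and 0.296%) and Trav4d-2 in 5 of 5 (0.274% and 0.221%). No test was made on these.

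Part of the Vα shift may follow from the Jα shift, since in WT cells at steady state the mean Jα number was 25.7 among distal and 37.9 among proximal Trav segments. With the Traj usage of each library set to the mean of its sampling, the difference in mean Vα rank was 2.04 of the 3.42 seen, and by pair of libraries 2.26, 2.18, 1.65, -0.0521, 3.73 and 2.46, so the test cannot tell the explanations apart. The shift does not rest on the 4 summed tables or on abundant pairs: outside these tables the smallest difference was 2.40, and without the 10 most abundant pairs it was 3.30.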
